A study of Homo sapiens with 6 samples.

How the data were processed

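RNA from BEAS2B cells was measured on 6 NimbleGen whole human genome arrays with a single Cy3 label, 3 from cells exposed to SWCNT and 3 from dispersant control cells. Per the labels' protocols, low-passage cells were exposed for 6 months to 0.02 micrograms per square centimetre of SWCNT, made from a stock of 0.1 mg/mL in water with Survanta, or to diluted Survanta alone, with matched passages. The design text calls the replicates biological, and the protocol describes triplicate dishes seeded from each treatment 3 passages after exposure. No separately exposed cultures are named, so the p-values measure the spread between these dishes.

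The deposited values are log2 values, 1 per probe set and array, normalized between arrays by the authors with RMA (background correction, quantile normalization and median polish), per the submitters' processing notes, which name RMA without a version. The software that read the images, any filter on probe sets and the genome build are not given in the sources used here. The table held 23953 probe sets with 0 missing values, and the lowest values sat near 6.23, a floor set by the normalization. No detection calls were used, so a value under the lower quartile of all values (6.84) was treated as dim and one over the upper quartile (9.21) as bright, and folds from dim values depend on the background correction. RMA makes the arrays' overall distributions alike, so a change of total RNA would not be seen. Array medians over all probe sets ran from 7.487 to 7.698. The number of arrays limits the precision: the median SE of a log2 difference was 0.33.

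Gene names came from the platform's annotation table for 9761 probe sets and, for 362 more, from a match of RefSeq accessions without versions to the RefSeq gene table of assembly GRCh38.p14, which was used for names and neighbour order only. In all, 10123 probe sets had 1 gene, 0 had several and 13830, or 57.7%, had none and were kept out of the gene comparison. Of the resulting 9404 genes, 596 had more than 1 probe set, and the probe set with the highest mean over the 6 arrays stood for the gene.

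The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment as the only term, 4 residual degrees of freedom with 5.08 prior ones), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. A second count asked for at least a 2-fold difference as well. In total 30 gene lists holding 602 distinct genes, of which 369 were measured, were fixed before the data were examined, and the 29 with at least 3 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Fry's PValue asks whether the genes of a list move on balance in one direction, without comparing them with other genes.

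The genes named were chosen by a rule fixed before the data were examined: the 8 largest rises and 8 largest falls past the threshold with no overlap between groups, uncharacterised symbols passed over, and in each list the up to 2 members past the threshold with the largest differences. This gave 55 genes, some of which are not reported here. Other list members were named as examples after their values were seen. Genes with near-identical relatives, such as AKR1C, SAA, HLA, histone and metallothionein genes, are uncertain, since a probe set may bind more than 1 of them.

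The alternatives were 2 further normalizations, 2 filters on dim genes, 3 other rules for probe sets, eBayes with trend and robust settings, array weights, the replicate number as a block, each array left out in turn, an adjusted p of 0.01, a fold of 1.5 and limma's treat against it. Chosen after the data were seen were quantile normalization over the named genes alone, dispersant arrays 1 and 2 averaged into 1 sample, and dispersant array 3 and SWCNT array 1 left out together. The replicate numbers did not pair the samples, and no block was used in the comparison.

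The procedure was tested on simulated data with the same 9404 genes and 3 arrays per group. Of 100 genes changed by 1 on the log2 scale it recovered 6, and of 100 changed by 2 it recovered 67, with 5 false calls among 78. Far fewer genes were changed than the 1198 called in the data, so the adjusted threshold was stricter in the simulation. The recovered shares therefore do not give the power in the data. The 1 list shifted in the simulation, by 1 on the log2 scale in every measured member, was the 1 called of 29. So even a shift makes a call nearly certain, and says little about lists in which only some members move. The simulated noise was independent between genes and alike on all arrays. The simulation therefore cannot show how the tests behave when the genes of a list are correlated or an array stands apart. In the data the estimated correlation within the proliferation list was 0.357. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.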

Results

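Gene expression was measured in BEAS2B cells, a human bronchial epithelial cell line immortalized with viral genes, after 6 months of culture with single-walled carbon nanotubes (SWCNT) or with the dispersant alone. SWCNT are hollow carbon fibres of nanometre width. They were given at 0.02 micrograms per square centimetre, dispersed in Survanta, a lung surfactant preparation, and the control cells were passaged alongside with Survanta only. Both cultures had gone through 24 passages of treatment. RNA was taken 3 passages after the treatment ended, 24 hours after cells of each treatment were seeded into dishes in triplicate, so each group holds 3 arrays. The comparison addresses whether long exposure at a low dose leaves signals related to tumour formation. The arrays gave normalized log2 values with medians from 7.487 to 7.698, and 9404 genes could be compared by name.

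The SWCNT-exposed cells differed from the dispersant cells most in SPP1, the gene of the secreted phosphoprotein osteopontin, which was 239-fold higher, from a log2 value of 6.52 ± 0.22 to 14.42 ± 0.12 (mean ± SD, n = 3 in each group). GAL, which encodes the neuropeptide galanin, was 138-fold higher, COL8A1, a collagen gene, 72.1-fold, and MAGEB2, a cancer-testis antigen gene, 62.7-fold. BEX1 had the largest fall, to a level 88.2-fold lower, from 13.03 ± 0.18 to 6.57 ± 0.18. MYL9, which encodes a regulatory light chain of myosin, was 46.7-fold lower. Each of these genes lay on its side in all 3 arrays of the group, with no overlap between groups, which the rule that chose them required.

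As log2 differences between SWCNT and dispersant (± SE from the model, n = 3 per group), the 8 largest rises were SPP1 (7.90 ± 0.26), GAL (7.11 ± 0.27), COL8A1 (6.17 ± 0.34), MAGEB2 (5.97 ± 0.28), AKR1C1 (5.94 ± 0.26), S100A4 (5.77 ± 0.29), GALC (5.75 ± 0.29) and AKR1C2 (5.51 ± 0.26). AKR1C1 and AKR1C2 encode aldo-keto reductases of steroid and carbonyl metabolism, S100A4 a calcium-binding protein, and GALC a lysosomal galactosylceramidase, while L1CAM, among the falls, encodes a cell adhesion protein. The 8 largest falls were BEX1 (-6.46 ± 0.26), the secernin gene SCRN1 (-5.82 ± 0.33), SAA2 (-5.67 ± 0.33), L1CAM (-5.55 ± 0.34), MYL9 (-5.55 ± 0.34), SAA1 (-5.25 ± 0.53), CRIP2 (-4.83 ± 0.34) and DKK3 (-4.71 ± 0.26). SAA1 and SAA2 encode acute-phase serum amyloid A proteins, CRIP2 a LIM-domain protein, and DKK3 a secreted protein of the dickkopf family. In limma's test with Benjamini-Hochberg adjustment the adjusted p of these 16 genes ran from 1.98e-06 for SPP1 to 4.12e-04 for SAA1. SPP1, GAL, COL8A1 and MAGEB2 in the dispersant cells, and BEX1 and DKK3 in the SWCNT cells, lay under 6.84, the lower quartile of all values, as did TWIST1, LOX, CCL2, CCN1, JUN, TJP1 and GCLM in the SWCNT cells, NANOG in the dispersant cells and POU5F1 in both, among the genes named below. The sizes of all their differences depend on how the deposited normalization treated background. The other probe set of L1CAM, at -1.50, differed in size from the one used, and with it the adjusted p was 0.0601, against a range from 4.64e-09 to 0.0601 over the alternatives tried. SAA1's other probe set was at -3.18, a smaller fall than that of the one used. The SAA1 and SAA2 transcripts are near-identical, as are those of AKR1C1 and AKR1C2, and a probe set may bind both members of a pair.

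**Figure D1:**
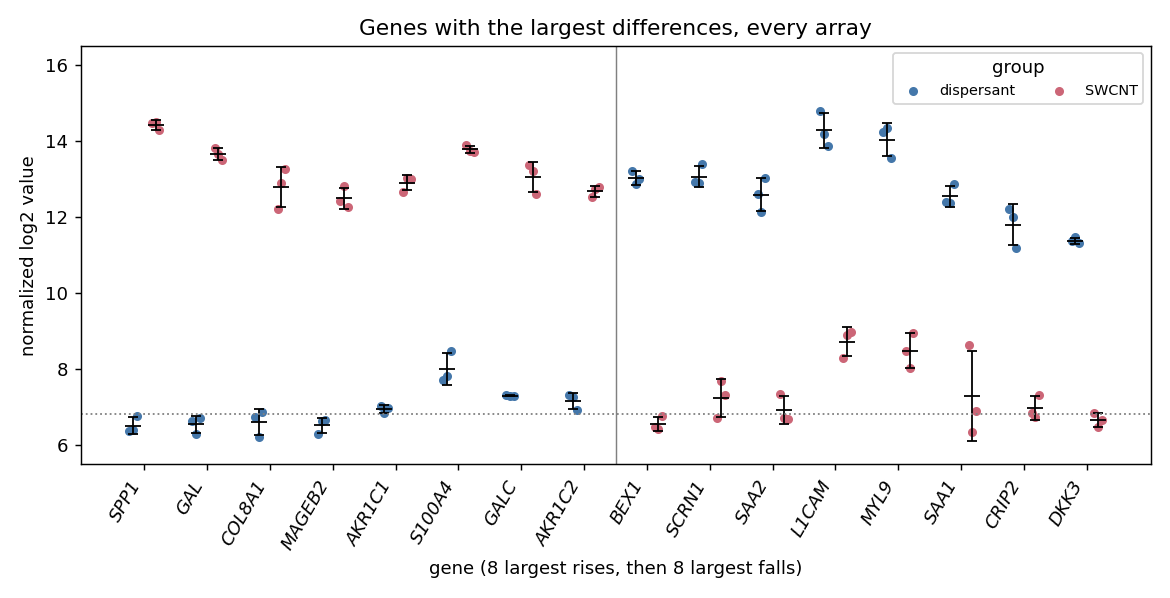
Normalized log2 values (y axis) of the 8 genes with the largest rises and the 8 with the largest falls (x axis) on each of the 3 dispersant and 3 SWCNT arrays. Points are arrays, bars the mean ± SD of a group, and the dotted line the lower quartile of all values, 6.84. SPP1 lay at 6.52 ± 0.22 in dispersant and 14.42 ± 0.12 in SWCNT. The rule that chose the 16 genes required that the groups not overlap.

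Across the genome, 1198 of 9404 genes, or 12.7%, passed an adjusted p of 0.05. Of these, 398 were higher in the SWCNT-exposed cells and 800 lower, so that 33.2% of the calls were rises. A second quantile normalization over the named genes alone, chosen after the data were seen, gave 571 rises and 625 falls, with 47.7% rises, and moved the median log2 difference of all genes by 0.105 from -0.09. At least 2-fold differences that passed the test numbered 1167, with 381 rises and 786 falls, and 109 genes differed at least 8-fold, 42 upward and 67 downward. In 2830 genes, or 30.1%, the groups did not overlap, where chance gives 10%. The count of 1198 moved by more than 1.5 times when single arrays were left out, to 501 without dispersant array 1, 533 without dispersant array 2, 2101 without dispersant array 3, 684 without SWCNT array 2 and 745 without SWCNT array 3. There was one exposed and one control culture as far as the labels tell, so p-values measure the spread between dishes, and the treatment cannot be told apart from other changes that arose in either culture over 24 passages.

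Genes of the NRF2 antioxidant response, the programme that cells switch on against oxidants and electrophiles, included some of the largest rises. The list passed camera (adjusted p 7.34e-09, median log2 difference 1.17) but not at adjusted p = 0.165 with an estimated correlation. Of 20 measured members, 9 rose, 0 fell and 11 did not pass, and adjusted over the list alone 11 rose and 0 fell. The 3 aldo-keto reductases of the list led, with AKR1C1 at 5.94 ± 0.26, AKR1C2 at 5.51 ± 0.26 and AKR1C3 at 4.90 ± 0.32. UGDH, which makes UDP-glucuronic acid for conjugation, rose by 3.04 ± 0.37, and TALDO1, an enzyme of the pentose phosphate pathway, by 1.99 ± 0.29. The cystine transporter gene SLC7A11 (1.65 ± 0.41), the thioredoxin gene TXN (1.36 ± 0.30), the peroxiredoxin gene PRDX1 (1.30 ± 0.26) and the ferritin light chain gene FTL (0.90 ± 0.25) also passed. Other well-known members did not, such as NQO1 at 1.25 ± 0.49 (adjusted p = 0.138), HMOX1 at 0.30 ± 0.41 and GCLM at -0.26 ± 0.32. AKR1C1, AKR1C2, AKR1C3, UGDH and TALDO1 passed whichever single array was left out, whereas FTL was lost without any single one of the 6 (adjusted p up to 0.165). TXN was lost without dispersant array 1 or 2 or SWCNT array 1 or 2 (up to 0.0973), SLC7A11 without dispersant array 1 or 2 or SWCNT array 2 or 3 (up to 0.118), and PRDX1 without dispersant array 1 or 2 (up to 0.0513).

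Several cell cycle and DNA replication genes fell in the SWCNT-exposed cells. The list passed camera (adjusted p 2.86e-05, median -1.13) but neither fry (0.126) nor camera at adjusted p = 0.889 with an estimated correlation. Of 31 measured proliferation genes, 0 rose, 10 fell and 21 did not pass, and adjusted over the list alone 14 fell. The largest falls were in KIF11 (-2.22 ± 0.47), a mitotic spindle motor, and MCM2 (-2.10 ± 0.39), a subunit of the replicative helicase. NUSAP1 (-2.00 ± 0.40), KIF20A (-1.96 ± 0.30) and CCNB1 (-1.50 ± 0.28), which act in mitosis, fell too, while PCNA was at -0.36 ± 0.45 and MCM6 at 0.34 ± 0.30 without passing. Dispersant array 3 itself had these genes lower than dispersant arrays 1 and 2, by a median of -1.05, where all genes had -0.12. Without dispersant array 3 the median of the list was -1.40. The call of KIF11 was lost without dispersant array 1 or 2 (adjusted p up to 0.0639) and that of NUSAP1 without dispersant array 1 or 2 or SWCNT array 2 (up to 0.0589), whereas MCM2, KIF20A and CCNB1 passed whichever single array was left out.

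Inflammatory genes moved in both directions. Of 17 cytokine and chemokine genes, 4 rose, 2 fell and 11 did not pass, and adjusted over the list alone 5 rose and 3 fell. The neutrophil chemokine gene CXCL5 rose by 3.01 ± 0.27, LIF by 2.69 ± 0.30 and IL6 by 2.01 ± 0.40. The adhesion receptor gene ICAM1 (-3.64 ± 0.50) and the monocyte chemokine gene CCL2 (-3.34 ± 0.41) fell. Among 12 interferon-stimulated genes 1 rose and 3 fell, and adjusted over the list alone 1 rose and 5 fell. The exonuclease gene ISG20 was higher by 2.74 ± 0.25 and IFI6 lower at -1.51 ± 0.32. IFI6 was lost without dispersant array 2 or SWCNT array 2 or 3 (adjusted p up to 0.072). By camera the adjusted p was 0.273 for the cytokine list and 0.620 for the interferon list.

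Genes of cell shape, adhesion and matrix also changed in both directions. Of 9 mesenchymal genes 2 rose and 3 fell (list alone: 2 and 4), with S100A4 at 5.77 ± 0.29 and the transcription factor gene TWIST1 at -3.27 ± 0.25, and the crosslinking enzyme gene LOX at -1.68 ± 0.31. Of 10 measured epithelial junction and keratin genes 0 rose and 2 fell, and 3 fell when adjusted over the list alone. Only 9 of 20 mesenchymal and 10 of 24 epithelial list members were measured. Major markers such as CDH1, EPCAM and OCLN were not among them, so the lists do not assess epithelial or mesenchymal state. The keratin gene KRT7 (-2.99 ± 0.32) fell, while KRT8 was at -0.10 ± 0.26 and TJP1 at -0.28 ± 0.33 without passing, and dispersant array 3 stood at a median of -0.39 against dispersant arrays 1 and 2 in this list. Among 9 matrix metalloproteinases and inhibitors 1 rose and 2 fell, and 2 and 3 adjusted over the list alone. The protease inhibitor gene SERPINE2 rose by 3.59 ± 0.54, whereas PLAUR, the urokinase receptor gene, was at -2.10 ± 0.34. Of 12 collagen, laminin and integrin genes 1 rose and 2 fell, as they did adjusted over the list alone. The collagen gene COL6A1 (-1.70 ± 0.31) and the integrin gene ITGAV (-1.96 ± 0.49) fell, the latter lost without dispersant array 1 or 2 or SWCNT array 1 or 3 (adjusted p up to 0.106). By camera these 4 lists had adjusted p values between 0.620 and 0.868.

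Of 12 measured genes of the TGF-beta target list 1 rose and 3 fell, and adjusted over the list alone 1 rose and 5 fell. The matricellular gene CCN1 (-3.99 ± 0.38) fell, and ID2, an inhibitor of basic helix-loop-helix factors, rose by 2.73 ± 0.30. Dispersant array 3 itself was lower in this list than dispersant arrays 1 and 2, by a median of -0.43. Camera gave the list an adjusted p of 0.0740. Under the quantile normalization over the named genes alone it was 0.0474, within a range from 0.0474 to 0.889 over all alternatives. Of 6 targets of the aryl hydrocarbon receptor 1 rose, the cytochrome gene CYP1B1 (2.71 ± 0.32), and adjusted over the list alone 2 rose. That list had a camera adjusted p of 0.128.

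Genes of cell death and DNA damage gave calls mostly downward or in both directions. Falls also outnumbered rises over all genes, where 12.7% passed and 33.2% of the calls were rises. Of 16 p53 targets 0 rose and 2 fell, also adjusted over the list alone, PPM1D (-1.72 ± 0.36), a phosphatase that damps the p53 response, and BBC3 (-1.24 ± 0.34), a cell death gene. Of 7 anti-apoptotic genes 0 rose and 1 fell, BIRC5 (-0.99 ± 0.27), which also acts in cell division, and adjusted over the list alone 1 rose and 2 fell. Of 21 pro-apoptotic genes 2 rose and 2 fell, also adjusted over the list alone, with BAD at -1.25 ± 0.28 and BBC3 among the falls. Of 23 DNA repair genes 1 rose and 2 fell, and 2 and 4 adjusted over the list alone, with the Fanconi anaemia gene FANCA at 0.96 ± 0.26. None of the 4 lists passed camera, with adjusted p between 0.569 and 0.868. Dispersant array 3 differed from dispersant arrays 1 and 2 by medians of -0.56 in the p53 targets, -0.43 in the anti-apoptotic, -0.32 in the pro-apoptotic and -0.52 in the DNA repair genes. The calls named here were lost when some single arrays were left out. That also leaves only 2 arrays in a group, so a lost call need not mean that 1 array carried it. The log2 difference of BIRC5 then ran from -1.13 to -0.91 and that of FANCA from 0.86 to 1.05. BBC3 was lost without dispersant array 1 or 3 or any SWCNT array (adjusted p up to 0.154), BIRC5 without dispersant array 1 or 2 or any SWCNT array (up to 0.176), and PPM1D without dispersant array 1 or SWCNT array 3 (up to 0.0608). BAD was lost without dispersant array 1 or 2 or SWCNT array 1 or 2 (up to 0.0997), and FANCA without dispersant array 1 or 2 or any SWCNT array (up to 0.183).

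Among growth regulators, 2 of 11 ERBB and MAPK feedback genes rose and 0 fell, the cyclin gene CCND1 (2.22 ± 0.46) and SPRY4 (1.47 ± 0.28), which encodes an inhibitor of receptor tyrosine kinase signalling. Adjusted over the list alone 2 rose and 1 fell. Of 6 immediate-early genes MYC rose by 1.75 ± 0.44 and JUN was at -1.02 ± 0.28, and of 8 stem cell markers MYC rose and PLAUR fell. Adjusted over the list alone the immediate-early counts were the same and the stem cell list had 3 rises and 1 fall. The pluripotency genes NANOG (0.16 ± 0.33) and POU5F1 (0.18 ± 0.28) did not pass. MYC was lost without dispersant array 1 or 2 or SWCNT array 2 or 3 (adjusted p up to 0.116), CCND1 without SWCNT array 2 or 3 (up to 0.0661), SPRY4 without dispersant array 1 (0.0589) and JUN without dispersant array 1 or 2 or any SWCNT array (up to 0.176). The immediate-early genes of dispersant array 3 lay at a median of -0.47 against dispersant arrays 1 and 2. Camera gave an adjusted p of 0.620 for the ERBB and MAPK list, 0.868 for the immediate-early list and 0.290 for the stem cell list.

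In the stress lists, 3 of 12 heat shock genes rose and 0 fell, led by HSPD1, the mitochondrial chaperonin gene (2.24 ± 0.27), and HSPA4L (1.79 ± 0.33), and adjusted over the list alone 3 rose and 1 fell. Of 16 unfolded protein and ATF4 response genes 1 rose, SDF2L1 (1.27 ± 0.29), and 1 fell, PPP1R15A (-2.19 ± 0.26), which encodes a phosphatase subunit that restores translation, and adjusted over the list alone 2 rose and 2 fell. Dispersant array 3 stood at a median of -0.32 against dispersant arrays 1 and 2 in this list. Of 20 hypoxia and glycolysis genes 1 rose and 3 fell, and 2 and 4 adjusted over the list alone. The enolase gene ENO2 (-3.14 ± 0.41) and ADM (-2.32 ± 0.39), the adrenomedullin gene, fell, while LDHA was at -0.09 ± 0.29 without passing. Of 12 metallothionein and metal response genes 2 rose and 3 fell, and adjusted over the list alone 3 rose and 3 fell. The metal-binding genes MT1F (-2.62 ± 0.27) and MT2A (-1.80 ± 0.41) fell, with the caution that metallothionein transcripts are alike enough to share probes, and dispersant array 3 stood at a median of 0.65 above the other 2 dispersant arrays in this list. HSPA4L was lost without dispersant array 1 (0.0502), SDF2L1 without dispersant array 1 or 2 or SWCNT array 1 or 2 (adjusted p up to 0.107), and MT2A without dispersant array 1 or 2 or SWCNT array 2 or 3 (up to 0.0767). The camera adjusted p of these 4 lists lay between 0.534 and 0.803.

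In the housekeeping lists, 0 of 26 oxidative phosphorylation genes passed limma's test, adjusted over the list alone too, and 6 had an unadjusted p under 0.05. Of 30 ribosomal protein genes 2 rose, RPLP2 (1.07 ± 0.26) and RPS13 (0.96 ± 0.26), and 0 adjusted over the list alone, and both were lost without dispersant array 1 or 2 or any SWCNT array (adjusted p up to 0.148 and 0.183). The camera adjusted p of the ribosomal list was 0.0740, with 0.00733 in the robust trend fit and a range up to 0.762 over the alternatives. Of 16 cholesterol synthesis genes 0 rose and 2 fell, also adjusted over the list alone, with FDFT1, which encodes squalene synthase, at -1.53 ± 0.37, and dispersant array 3 stood at a median of -0.33 against the other 2 dispersant arrays. FDFT1 was lost without dispersant array 1 or 2 or SWCNT array 1 or 3 (adjusted p up to 0.116). Adjusted p by camera was 0.569 for oxidative phosphorylation and 0.868 for cholesterol synthesis.

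Measured markers of particular cell types gave no calls, and most members of each of these lists were not measured. None passed limma's test among 4 airway basal, 5 secretory and ciliated, 4 alveolar, 5 fibroblast, 5 leukocyte and 2 endothelial markers, over all genes or adjusted over the list alone, while 3 of them had an unadjusted p under 0.05. These 3 were the collagen gene COL1A1 at -0.74 ± 0.31, the club cell gene SCGB1A1 at 1.14 ± 0.39 and the tubulin gene TUBB4B at -1.46 ± 0.59. The camera adjusted p of the 5 lists tested lay between 0.569 and 0.898, and the endothelial list, with 2 measured members, was not tested.

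**Figure D2:**
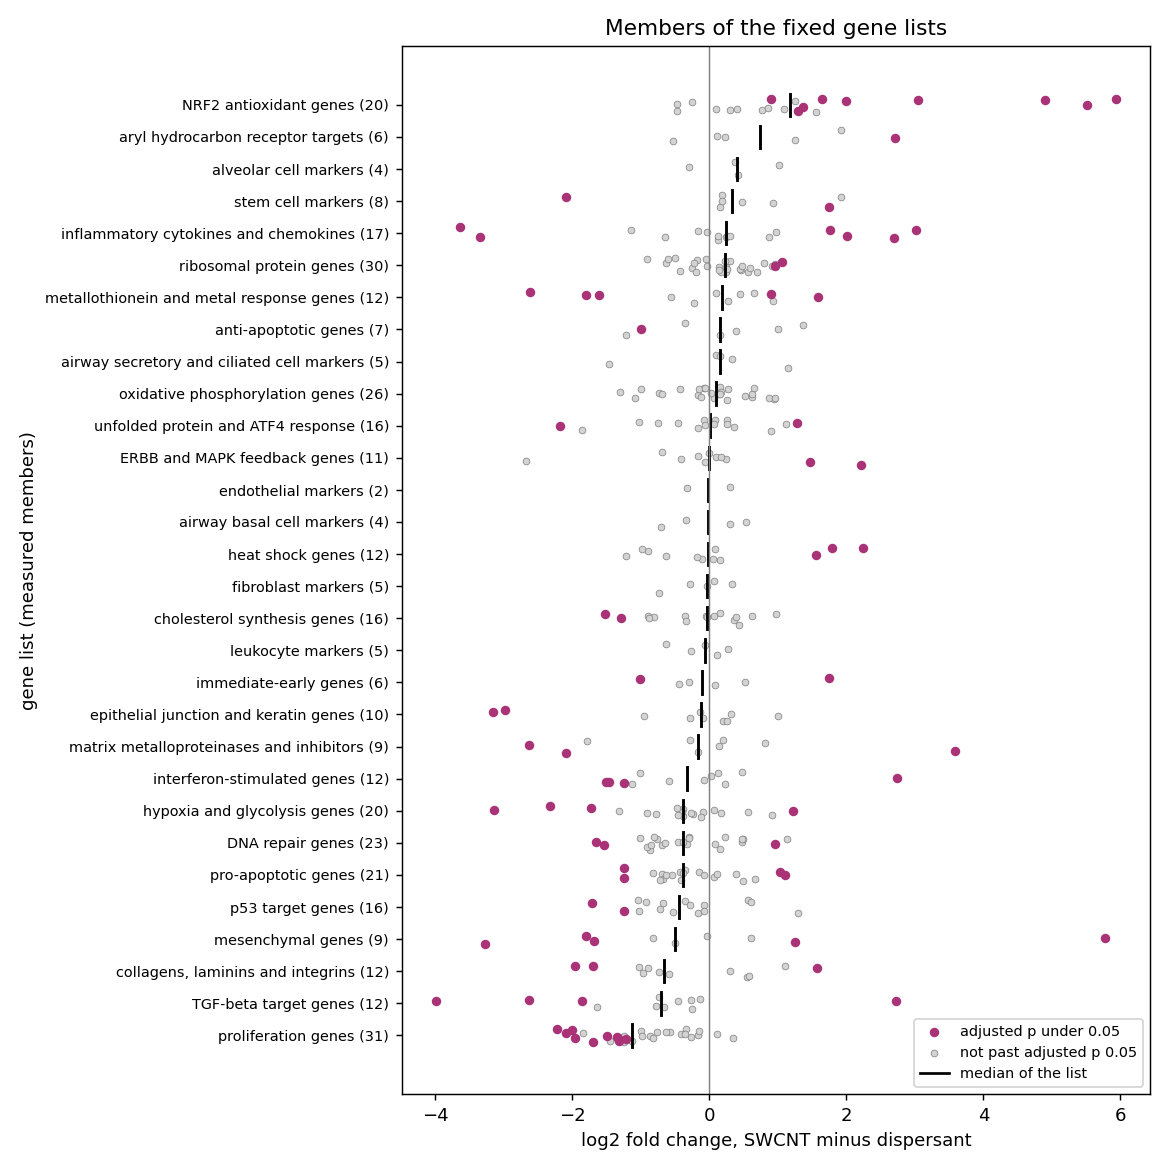
Log2 fold change, SWCNT minus dispersant (x axis), of each measured member of the 30 fixed gene lists (y axis, with the number measured). Filled points passed an adjusted p of 0.05, open grey points did not, and the black line is the median of the list. The NRF2 list, with a median of 1.17, lies at the top and the proliferation list, with -1.13, at the bottom.

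Of 29 lists tested, NRF2 antioxidant and proliferation were the 2 with a camera adjusted p under 0.05, and 0 passed with an estimated correlation, where 1 had an unadjusted p under 0.05 and fry passed 3. Median, mean and camera direction differed in sign for the airway basal, leukocyte, unfolded protein, ERBB and MAPK, immediate-early, heat shock and metallothionein lists. The sign of the median changed with the scaling for the basal, fibroblast, leukocyte, endothelial, cholesterol, ERBB and MAPK, and heat shock lists.

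The arrays separated by treatment on the first principal component, which held 58.2% of the variance of the named genes. The 3 dispersant arrays had scores of -54.9, -54.1 and -20.8 and the 3 SWCNT arrays 52.0, 36.4 and 41.5. Dispersant arrays 1 and 2 were close to each other, with a Pearson r of 0.979 across genes, which are not independent replicates, and an SD of their difference of 0.378. Dispersant array 3 correlated with them less closely, at 0.900 and 0.896, and it had a score of -51.7 on the second component, which held 19.6%. Among the SWCNT arrays r ran from 0.904 to 0.943, and between the groups from 0.789 to 0.850.

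**Figure D3:**
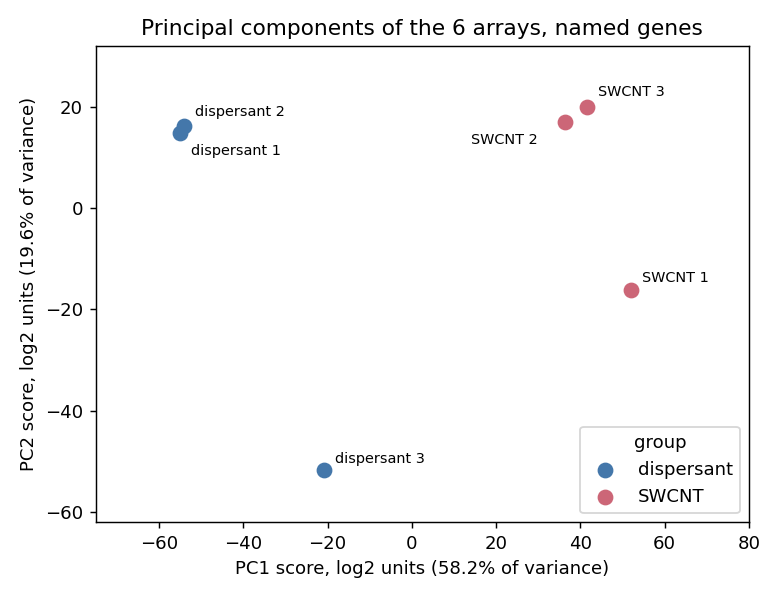
Scores of the 6 arrays on the first (x axis, 58.2% of the variance) and second (y axis, 19.6%) principal components of the log2 values of the named genes. Each point is an array, coloured by group; dispersant array 3, at -20.8 and -51.7, lies apart from dispersant arrays 1 and 2, and the groups do not overlap on the first component.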

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

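Probe sets without a gene name lay outside the gene comparison and carried signal that differed between the groups, so they were looked at on their own. Of 13830 such probe sets, 1299 passed limma's adjusted p of 0.05 in a fit over all probe sets, 600 higher in the SWCNT-exposed cells and 699 lower. Which transcripts they measure was not analysed here, and no explanation was tested.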

How the results depend on the processing

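The 3 alternatives named in processing as chosen after the data were seen are the averaged pair, the pair of arrays left out together and the normalization over the named genes. The count of 1198 genes, and that of 1167 changed at least 2-fold, stayed within 1.5 times under the 3 other normalizations, both filters on dim genes, the mean or the lowest-mean probe set and the robust trend fit. With every probe set tested on its own they were 2469 and 2414, out of 23953, and with array weights, which gave dispersant array 3 a weight of 0.31, 2786 and 2059. Leaving out each array in turn gave 501 to 2101 genes, and 501 to 1986 at 2-fold. The lowest came without dispersant array 1 (501) and dispersant array 2 (533), with 684 without SWCNT array 2 and 745 without SWCNT array 3, and the highest without dispersant array 3. Averaging dispersant arrays 1 and 2 into 1 sample gave 544 for both counts, and leaving out dispersant array 3 and SWCNT array 1 together gave 2307 and 2081. An adjusted p of 0.01 left 464 genes, and treat against a fold of 1.5 left 384. The NRF2 and proliferation lists kept camera's call in every alternative that tested them with camera at the preset correlation. With an estimated correlation 0 lists passed, with an adjusted p of 0.165 for NRF2 and 0.889 for proliferation. Fry passed 3 lists, NRF2, aryl hydrocarbon receptor targets and ribosomal proteins (both 0.0207), and not proliferation (0.126). Of the 55 named genes 33 kept their call in every alternative they were in, 22 lost it in at least 1, and 0 turned direction. BBC3 and BIRC5 missed the threshold under all 3 other normalizations and JUN under 2 of them. Among the 76 members of the fixed lists past the threshold, 31 passed whichever single array was left out. With the replicate number as a block 950 genes passed, all of them at 2-fold, 2 lists did, and 7 of the 55 named genes missed the threshold. The deviations of same-numbered arrays correlated at -0.218, 0.153 and -0.119, so the numbers were not taken as pairing. Why the counts moved was otherwise not tested. Genes near the floor of 6.23 limit what can be seen of small differences in dim transcripts.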

Other observations

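The gene lists below and all tests in this part except the splits of the arrays were chosen after the results were seen. Several genes of the contractile cytoskeleton fell in the SWCNT-exposed cells. Of 23 measured actomyosin genes 0 rose and 11 fell, among them MYL9 (-5.55 ± 0.34, ± SE, n = 3 per group), the tropomyosin genes TPM1 (-4.26 ± 0.36) and TPM2 (-2.73 ± 0.29) and the alpha-actinin gene ACTN1 (-2.57 ± 0.36), with a median of -1.35, and the list did not pass with an estimated correlation (adjusted p = 0.142 with an estimated correlation). Dispersant array 3 was itself lower in these genes than dispersant arrays 1 and 2, by a median of -0.73. Of 15 class I HLA and antigen presentation genes 0 rose and 6 fell, including HLA-C (-2.70 ± 0.57), the immunoproteasome gene PSMB9 (-2.38 ± 0.25) and TAPBP (-1.70 ± 0.29), at adjusted p = 0.228 with an estimated correlation. Here too dispersant array 3 was lower, by a median of -0.65.

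Of 47 replication-dependent histone genes 1 rose and 19 fell (camera adjusted p = 0.0510 with an estimated correlation, over the added lists alone). The falls lay in 11 of 14 H2B genes, 7 of 14 H2A genes and 1 of 4 linker histone genes, whereas 0 of 7 H3 genes and 0 of 8 H4 genes fell, and H4C14 rose by 1.28 ± 0.31. Whether the families differ was not tested, and dispersant array 3 itself stood at a median of -0.71 against dispersant arrays 1 and 2 in H2B, 0.35 in H2A and 0.79 in H3. H1-2 had the largest fall, at -3.27 ± 0.33. Of 16 cancer-testis antigen genes 3 rose, MAGEB2 (5.97 ± 0.28), MAGEA4 (2.67 ± 0.36) and MAGEB1 (2.14 ± 0.28), and 0 fell. The camera adjusted p of this list with an estimated correlation was 0.0510, over the added lists alone. Histone and HLA transcripts are alike within their families, so single members are uncertain, and MAGEB2 and MAGEB1 were dim in the dispersant cells, so the sizes of their rises depend on background.

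Dispersant array 3 lay apart from dispersant arrays 1 and 2, toward the SWCNT arrays on the first component. Other arrays stood apart as well. Genes beyond all other arrays by over 1 on the log2 scale numbered 225 for SWCNT array 1, 183 for dispersant array 3 and 175 for SWCNT array 3. RNA of exposed cells in dispersant array 3 is argued against as the whole cause of its position. Over 43 genes at least 8-fold higher in SWCNT, called without dispersant array 3, it exceeded the other 2 by a median of 0.35 (95% bootstrap interval 0.05 to 0.42), where a share of 10% would give 1.05. A share under that cannot lower genes by the median of -1.05 by which the 31 proliferation genes were lower in it. A smaller share is not excluded, and no biological explanation was tested. A factor shared with SWCNT array 1 stays open and may account for part of it, since the deviations of these 2 arrays from their groups correlated across genes at 0.27. The difference between dispersant arrays 1 and 2 gave at most 0.04. That comparison is weak, because dispersant arrays 1 and 2 were nearly alike, with an SD of their difference of 0.378. Dispersant array 3 and SWCNT array 1 also had the lowest medians over all probe sets, 7.507 and 7.487.

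The 4 measured AKR1C genes rose together, by 4.90 to 5.94. Cross-hybridisation cannot be told apart from a joint rise, because the 4 differed by only 1.05 and the probe sequences were not used here; AKR1C4, known mainly from liver, moved with the rest. A wider rise of NRF2 targets could be part of it. Without the AKR1C genes the list still stood higher, with a camera p of 4.1e-06 over 17 genes (median 0.90, 6 rose, 0 fell). With an estimated correlation its unadjusted p was 0.012, against 0.00569 for the full list, whose adjusted p of 0.165 did not pass. Whether exposure or another change in the cultures raised these genes is not separated by the design.

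Some genes moved between dim and bright. Of the called genes 28 were bright in dispersant and dim in SWCNT, such as PYCARD (10.97 to 6.52), ALDH2 (10.15 to 6.56) and IL7R (9.74 to 6.49), and 13 went the other way, such as CPS1 (6.50 to 11.14), NES (6.69 to 9.89) and NRG1 (6.75 to 9.53). A minority of other cells in the SWCNT dishes is argued against as the cause of the falls. In limma's treat 128 genes were lower by more than 2-fold, whereas the original cells would still supply most of the RNA. Such a minority is not excluded as a source of the rises. Another or a clonally expanded population in place of the original cells, and a response of all cells, cannot be told apart, because the labels name no separately exposed cultures.

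A hypothesis tied to this is that gains or losses of chromosome segments arose in one of the cultures, which may move neighbouring genes together. Between genes 20 measured places apart on the same chromosome, log2 differences correlated with a Spearman rho of 0.054 over 8931 pairs (p = 0.001, the smallest that 1000 permutations can give). Within groups the same measure was -0.002 for dispersant array 3 against 1 and 2, 0.012 for SWCNT array 1 against 2 and 3 and 0.016 for dispersant array 1 against 2. The rho exceeded the first, the lowest of them, by 0.024 to 0.086 (95% block bootstrap interval), and no interval was computed against the others. Any difference between the cultures could give such an excess over dishes of the same culture. Between adjacent genes the correlation was 0.132, higher than at 20 places. Leaving out histone genes gave 0.056. The correlation is small, genes are not independent replicates, and domains of shared regulation would give the same sign.

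Of the 10 splits of the 6 arrays into 3 and 3, the real one gave 1198 genes and the others at most 0, so 1 of 10 gave as many. At 2-fold the real split gave 1167 and the others at most 0, again 1 of 10. For gene lists the real split gave 2 and the others at most 2, and 3 of 10 gave as many. The splits are too few for a share under 0.05. Every other split also puts arrays of both treatments into each group, so the difference between treatments adds to the spread within groups. That alone lowers their gene counts, and no conclusion is drawn from them.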
